A study of Homo sapiens with 48 samples.

How the data were processed

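The series holds 48 libraries of MCF10A-1 cells, 24 for GRO-seq and 24 for RNA-seq, in 6 groups of 4 per assay (vector or SATB1 cells, untreated or with 4 µM benzo[a]pyrene for 3 hours or 3 days, per the labels). One label text gives the short exposure a length that differs from that in the titles and characteristics, which were followed. Nothing in the labels says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

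The files used here hold the authors' own comparisons. Per the file headers, each of the 2 tables gives, for 5 numbered contrasts, a fold change (a linear ratio) and an unadjusted p-value per gene symbol. The headers do not say which groups a contrast compares. Per the submitters' processing notes, BWA 0.7.16a, featureCounts and limma were used for GRO-seq and STAR and DESeq for RNA-seq, with the build GRCh38; the order, settings, annotation and filters are not given in the sources used here. The p-values the authors deposited carry the column name that limma gives an unadjusted p. Whether counting used the strand is not stated, so overlapping and antisense genes and near-identical family members such as keratins are uncertain. Values per library were not used here, so the depth is unknown, and no SD, replicate left out, block, other split of the libraries or count model was possible. The planned fits on libraries were replaced by the planned fallback, the deposited comparisons, and lists were tested by counts in place of camera and fry.

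From these values, p-values were adjusted by the Benjamini-Hochberg method within a contrast over all rows with a gene symbol, and a gene was called at an adjusted p under 0.05. In RNA-seq, 156 rows without a symbol (0.994%) were left out, and 23 rows whose symbol had become a date were tested but not named. Symbols on more than 1 row were left out of lists and joins, which left 14743 genes in GRO-seq and 15498 in RNA-seq. Of these, 96.2% and 96.3% matched a symbol of GRCh38.p14, from which coordinates were taken. Log2 fold changes were computed from the deposited ratios. The implied standard error of a log2 fold change is its size divided by the quantile of Student's distribution at the deposited p-value, with the degrees of freedom (25 in GRO-seq and 30 in RNA-seq) at which a gene's 5 standard errors varied least. It is the error given after ±. The difference of 2 contrasts was tested with the standard errors of both, taken as independent, and adjusted over all genes. With a positive covariance from a common group that test calls too few genes, and with a negative one too many.

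There were 21 gene lists fixed before the data were examined, as were the named genes, thresholds and most alternatives. Called members, higher and lower apart, were compared with all other tested genes by a two-sided Fisher's exact test, adjusted over lists and directions within a contrast. Genes of a list are not independent, so these p-values describe the tables. List medians were also set among those of 10000 random lists of the same size. The named genes are SATB1, CYP1A1, CYP1B1, TIPARP, CDH1, VIM and SNAI2, those with the 6 largest and 6 smallest fold changes among called genes, and up to 4 called members with the smallest adjusted p of each list with at least 3 called. The larger number of extremes was meant for the main comparisons and was applied to all contrasts, since the headers do not identify them; the text gives part of the genes so chosen. Of the genes so chosen, 1 is not reported here. No mean level is given in the tables, so no filter on level was made. The EMT set compiled by the study is not marked in the tables and was not used here. The more precisely measured genes are those with an implied standard error at or below the table's median, an alternative chosen after seeing the data, with p-values adjusted again over them. Percent intervals of shares are exact binomial ones, except those of chromosomes, which are Wilson intervals.

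The steps were tested on simulated data with 200 changed genes on the real standard errors. For a single contrast, 28 of 100 genes changed by log2 1 and 73 of 100 changed by log2 2 were called over 14743 GRO-seq genes, with 5 unchanged genes among 106 calls. Over 15498 RNA-seq genes, 77 and 88 of 100 were called, with 11 unchanged genes among 176 calls. The difference test called 0 genes where none was planted, and 112 of 200 (GRO-seq) and 161 of 200 (RNA-seq) of log2 2. Alternatives were an adjusted p under 0.01 or 0.1, a minimum of 1.5-fold or 2-fold, adjustment over all rows, genes called in either assay, the more precisely measured genes, and the genes off chromosomes 15 and 17. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.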

Results

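Nascent transcription and accumulated mRNA were measured in MCF10A-1, a human breast epithelial cell line, carrying either an empty vector or a construct that stably expresses SATB1, a nuclear protein that organises chromatin. Cells were left untreated or exposed to 4 µM benzo[a]pyrene, a polycyclic aromatic hydrocarbon that activates the aryl hydrocarbon receptor (AHR), for 3 hours or 3 days. GRO-seq captures RNA that engaged polymerases extend in isolated nuclei, and RNA-seq measures the mRNA pool. Each assay had 24 libraries in 6 groups of 4. The study asked which genes of the epithelial-to-mesenchymal transition (EMT) respond to SATB1 or to benzo[a]pyrene. Results are drawn from the authors' deposited table for each assay, which lists a fold change and an unadjusted p-value per gene for 5 numbered contrasts. The table headers do not say which groups a contrast compares, so contrasts are named by number, and higher or lower means a fold change above or below 1. The depth of the libraries is unknown. The standard error behind a fold change was derived from the fold change and its p-value, and its median was 0.32 on the log2 scale in GRO-seq (14745 genes) and 0.058 in RNA-seq (15535 genes with a symbol). Calls are at a Benjamini-Hochberg adjusted p under 0.05.

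The number of genes called differed widely between contrasts. In GRO-seq, 116 genes were called in contrast 1 (43 higher, 73 lower), 2280 in contrast 2 (1125 higher, 1155 lower), 2676 in contrast 3 (1361 higher, 1315 lower), 458 in contrast 4 (233 higher, 225 lower) and 35 in contrast 5 (17 higher, 18 lower). In RNA-seq, the counts were 6818 (3600 higher, 3218 lower), 2993 (1497 higher, 1496 lower), 5607 (2849 higher, 2758 lower), 1362 (601 higher, 761 lower) and 3332 (1631 higher, 1701 lower). Most called RNA-seq changes were small: the median size of a called change lay between 1.13-fold and 1.19-fold, against 2.01-fold to 2.67-fold in GRO-seq. With the larger standard errors of GRO-seq only larger changes can be called, so these sizes do not show that changes differ in size between the assays. With a minimum of 2-fold, the RNA-seq counts were 1042, 117, 287, 43 and 144.

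**Figure D1:**
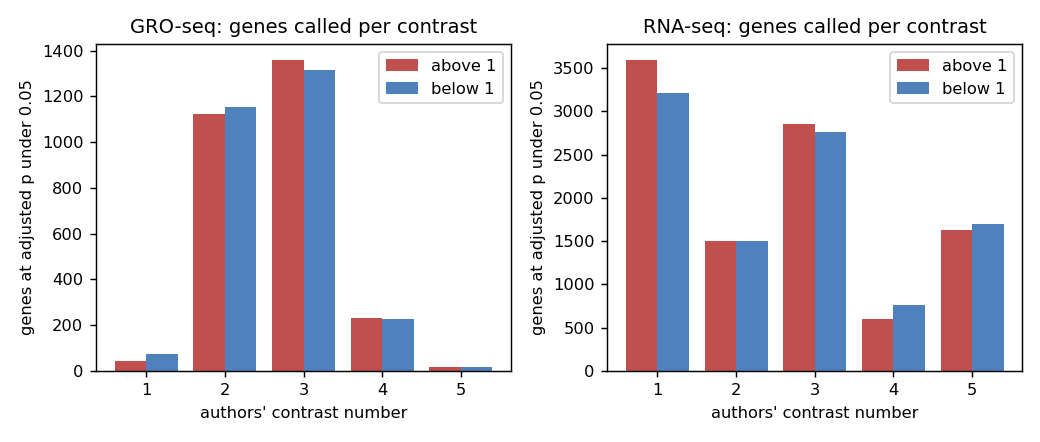
Number of genes above 1 (red) and below 1 (blue) at an adjusted p under 0.05 in each of the authors' 5 numbered contrasts, for GRO-seq (left) and RNA-seq (right, on its own scale). Contrast 3 has the most GRO-seq calls (2676) and contrast 1 the most RNA-seq calls (6818).

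Contrast 1 was the contrast with a large change of SATB1. SATB1 (chromosome 3, 18345377 to 18445592, GRCh38) was 112-fold higher in RNA-seq in the authors' deposited table (log2 fold change 6.81 ± 0.14 implied standard error, adjusted p = 2.3e-26), and was not analysed in GRO-seq here. CYP1A1, a cytochrome P450 induced through AHR, was not called in either assay (1.46-fold in RNA-seq, adjusted p = 0.12). The AHR-induced genes as a list leaned higher, with a median log2 fold change of 0.50 in RNA-seq and 0.41 in GRO-seq. These medians lay at percentiles 100 and 98.9 among random lists. By counts the list did not pass, with 7 of 15 higher and 3 lower in RNA-seq (adjusted p = 0.17 for higher, Fisher's exact test). In GRO-seq, none of 13 was higher and 1 was lower. The largest RNA-seq increases in the authors' deposited table were those of the neutrophil chemokine CXCL5 (2178-fold), the gap junction gene GJA1 (809-fold), the collagen genes COL1A2 (681-fold) and COL3A1 (379-fold), the lipid droplet gene PLIN2 (501-fold) and the scavenger receptor gene CD163 (302-fold). The largest decreases were those of ADH1B (0.00726-fold), CADM3 (0.00887-fold), ACMSD (0.0121-fold), ACKR1 (0.0168-fold), CHDH (0.0345-fold) and SULT1E1 (0.0463-fold). The implied standard error of the log2 fold change was 0.56 for CXCL5, and the tables used here give no levels behind these ratios. MTAP (31.1-fold), CDKN2A (301-fold) and CDKN2B (50.4-fold), chosen after their values were seen and lying in a region reported as deleted in MCF10A cells, were also higher in the authors' deposited table. Whether the cells on both sides of contrast 1 are the same line was not tested, which bears on each value of this contrast.

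EMT-related groups shifted in RNA-seq contrast 1. Of 39 mesenchymal and matrix markers, 26 were higher and 5 lower (adjusted p = 1.3e-07 for higher, Fisher's exact test), with a median log2 fold change of 0.57. COL1A1 was 12.1-fold, SPARC 37.2-fold and COL5A2 3.83-fold higher in the authors' deposited table, whereas S100A4 (0.507-fold) and CDH2, which encodes N-cadherin (0.614-fold), were lower. Of 33 epithelial markers, 20 were lower and 4 higher (adjusted p = 7.2e-06 for lower). They included the tight junction gene CLDN1 (0.433-fold), the desmosome genes DSP (0.641-fold) and JUP (0.649-fold), and CDH1, which encodes E-cadherin (0.662-fold, log2 -0.60 ± 0.03, adjusted p = 9.4e-17). The mesenchymal marker VIM (1.11-fold) and the EMT transcription factor gene SNAI2 (1.18-fold) were higher by smaller amounts. EMT transcription factors as a group did not pass, with 7 of 18 higher and 3 lower (adjusted p = 0.28 for higher), although PRRX1 was 99.1-fold and ETS1 1.74-fold higher in the authors' deposited table. Among 9 fibroblast markers, 6 of which are also in the mesenchymal list, 5 were higher and 1 lower (adjusted p = 0.15 for higher). The proteoglycan gene DCN was 0.125-fold, and LUM, chosen after its value was seen (0.479-fold, adjusted p = 0.29), was not called. The epithelial call was lost among the more precisely measured genes (10 of 18 lower, adjusted p = 0.068).

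Cell cycle genes were higher and p53 target genes lower in RNA-seq contrast 1. Of 33 DNA replication and mitosis genes, 28 were higher and 1 lower (adjusted p = 4.4e-12), by small amounts such as 1.43-fold for the ribonucleotide reductase gene RRM2 and 1.33-fold for AURKB in the authors' deposited table, and none by 2-fold. Of 30 genes activated by p53, 23 were lower and 5 higher (adjusted p = 1.6e-09 for lower), among them TP53INP1 (0.443-fold), TP53I3 (0.579-fold) and SESN1 (0.636-fold). Cytokine and NF-κB target genes were higher in 12 of 19 cases (adjusted p = 0.0019), including IL24 (6.41-fold), LIF (1.91-fold) and IL1B (1.57-fold). Neither p53 targets, cell cycle genes nor cytokine genes passed when 2-fold was also required (adjusted p = 0.995, 0.995 and 0.25). The basal keratin genes KRT15 (0.202-fold), KRT14 (0.568-fold) and KRT5 (0.727-fold) were lower in the authors' deposited table, but basal markers as a group did not pass (6 higher and 7 lower of 14, adjusted p = 0.084 for lower). The Notch receptor gene NOTCH3 was 0.222-fold in the authors' deposited table.

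In GRO-seq contrast 1, cell cycle genes and p53 targets lay on the opposite side to RNA-seq. The cell cycle median was -0.32 (percentile 0.02 among random lists, against 0.19 and percentile 99.9 in RNA-seq), and the p53 median was 0.20 (percentile 97.0, against -0.26 and percentile 0 in RNA-seq). Mesenchymal markers had a median of 0.48 (percentile 100) and epithelial markers of -0.13 (percentile 6.57). By counts of called genes, no list passed there. The genes with the largest folds among its 116 calls were CLGN (11.6-fold), IL24 (9.91-fold) and the interleukin-7 receptor gene IL7R (9.40-fold), and those with the smallest were the cyclin-dependent kinase inhibitor gene CDKN1C (0.0427-fold), ACMSD (0.0648-fold) and SCNN1G (0.101-fold) in the authors' deposited table. CDH1 was 0.497-fold (log2 -1.01 ± 0.38, adjusted p = 0.21), VIM 1.33-fold (adjusted p = 0.75) and SNAI2 0.855-fold (adjusted p = 0.85). At an unadjusted p under 0.05, 2162 genes passed, against 737 by chance. At an adjusted p under 0.01, 1 gene was left.

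In contrast 2, CYP1A1 had the largest fold in both assays, and AHR target genes the 3 largest in GRO-seq. CYP1A1 (chromosome 15, 74719542 to 74725528, GRCh38) was 163-fold higher in GRO-seq (log2 7.35 ± 0.76, adjusted p = 5.9e-07) and 195-fold higher in RNA-seq (log2 7.61 ± 0.22, adjusted p = 3.6e-22) in the authors' deposited table. CYP1B1 (chromosome 2, 38067509 to 38076151) was 20.7-fold and 7.60-fold higher, and TIPARP, an ADP-ribosyltransferase gene (chromosome 3, 156674590 to 156706770), 3.65-fold and 2.12-fold. AHRR, the AHR repressor gene, was 33.9-fold higher in GRO-seq. Of the AHR-induced genes, 8 of 13 were higher and 1 lower in GRO-seq (adjusted p = 4.3e-05) and 11 of 15 were higher in RNA-seq (adjusted p = 2.5e-07). The GRO-seq call was lost among the more precisely measured genes, which hold 3 of the 13, 2 of them higher (adjusted p = 0.39). SATB1 was not called in RNA-seq (1.05-fold, adjusted p = 0.86).

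**Figure D2:**
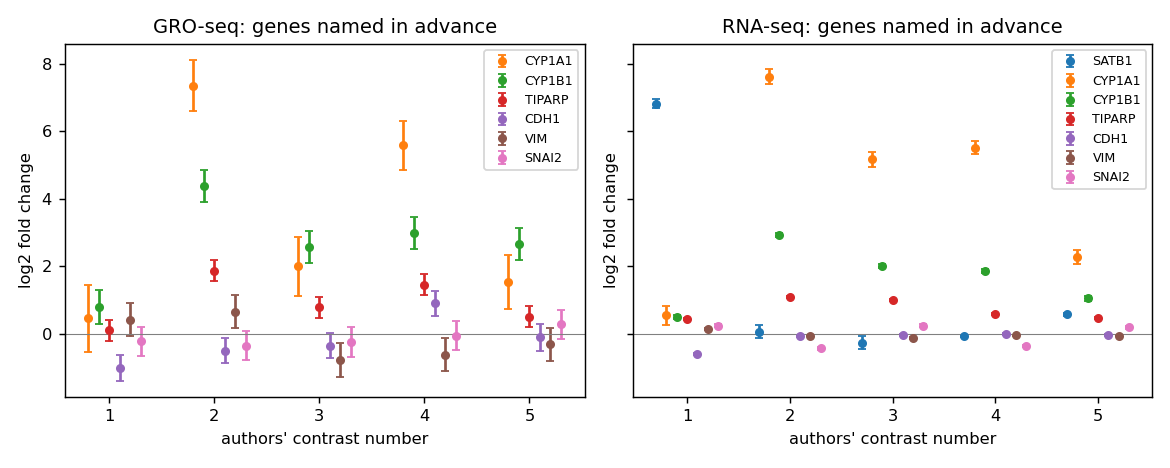
Log2 fold change (points) and implied standard error (bars) of the genes named before the data were examined, by contrast number, in GRO-seq (left, without SATB1) and RNA-seq (right). CYP1A1 lies highest in contrasts 2 and 4 of both assays, and SATB1 reaches 6.81 in RNA-seq contrast 1.

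Other genes at the extremes of contrast 2 in GRO-seq were the nebulin gene NEB (19.0-fold), the transcriptional coactivator gene PPARGC1A (14.2-fold) and DCN (12.8-fold), and among the lowest INSC (0.0509-fold), the lipoprotein lipase inhibitor gene ANGPTL4 (0.0528-fold), KRT13 (0.0814-fold) and CXCL1 (0.0919-fold), all from the authors' deposited table. In RNA-seq they were HSPA6 (17.4-fold), TEX14 (9.89-fold), CLDN9 (9.66-fold) and CD7 (8.36-fold), against CABP7 (0.164-fold) and AMOT (0.237-fold). Reads of HSPA6 can be shared with its near-identical heat shock relatives, so its value is uncertain.

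Immediate early and p53 target genes were higher in contrast 2, and TGF-β pathway genes lower. Immediate early genes were higher in 8 of 21 cases in GRO-seq (adjusted p = 9.7e-04) and 10 of 21 in RNA-seq (adjusted p = 1.2e-04), with EGR1 4.04-fold and 1.74-fold and FOSB 9.58-fold in GRO-seq. In RNA-seq, 5 were lower, including MYC (0.640-fold) and KLF6 (0.712-fold) in the authors' deposited table. Of the p53 targets, 10 of 30 were higher in each assay (adjusted p = 9.7e-04 in GRO-seq and 0.0034 in RNA-seq), with 1 lower in GRO-seq and 3 in RNA-seq. XPC, a DNA damage recognition gene, was 2.23-fold and CCNG1 2.95-fold higher in GRO-seq, and CDKN1A, which encodes p21, 1.46-fold higher in RNA-seq. TGF-β pathway genes were lower in 9 of 25 cases in GRO-seq (4 higher, adjusted p = 9.7e-04 for lower) and 11 of 25 in RNA-seq (3 higher, adjusted p = 1.2e-04 for lower). The activin subunit gene INHBA was 0.114-fold and 0.594-fold, PMEPA1 0.327-fold and SMAD3 0.398-fold in GRO-seq, and the receptor gene TGFBR2 0.772-fold in RNA-seq, in the authors' deposited table.

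EMT transcription factor genes were lower in 6 of 17 cases in GRO-seq contrast 2 (2 higher, adjusted p = 0.011, and 1 of 17 at an adjusted p under 0.01, where the call was lost) and in 6 of 18 in RNA-seq (3 higher, adjusted p = 0.037). ETS1 was 0.214-fold, ZEB2 0.308-fold and ZEB1 0.484-fold in GRO-seq, whereas in RNA-seq SOX9 was 0.484-fold, FOXC2 0.596-fold, SNAI2 0.743-fold (log2 -0.43 ± 0.04, adjusted p = 3.1e-09) and RUNX2 1.98-fold in the authors' deposited table. Mesenchymal markers did not pass in GRO-seq (8 of 38 lower and 2 higher, adjusted p = 0.057 for lower), although TNC (0.107-fold), TAGLN (0.203-fold), COL4A1 (0.229-fold) and COL4A2 (0.213-fold) were lower. CDH1 and VIM were called in neither assay. Basal markers were lower in 6 of 14 cases in RNA-seq (adjusted p = 0.010), with TP63 0.716-fold and ITGB4 0.890-fold but KRT17 1.16-fold. Cytokine genes in RNA-seq went both ways, with 6 of 19 higher, such as IL24 (5.22-fold), and 5 lower, such as CXCL8 (0.575-fold), with a median of -0.01 (adjusted p = 0.043 for higher). Among the more precisely measured genes, with fewer members tested, the EMT factor calls (3 of 8 lower in GRO-seq, adjusted p = 0.48, and 4 of 7 in RNA-seq, adjusted p = 0.16) and the immediate early call in GRO-seq (5 of 13 higher, adjusted p = 0.23) were lost. So were the p53 (6 of 24), basal (6 of 11) and cytokine (3 of 7) calls in RNA-seq (adjusted p = 0.48, 0.053 and 0.37). No RNA-seq list but the AHR list passed with a 2-fold minimum.

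In contrast 3, CYP1A1 was 36.0-fold higher in RNA-seq (log2 5.17 ± 0.22, adjusted p = 8.7e-18), while GRO-seq gave 3.99-fold (log2 2.00 ± 0.88, adjusted p = 0.12) in the authors' deposited table. CYP1B1 was 5.95-fold higher in GRO-seq and 4.02-fold higher in RNA-seq, the aldehyde dehydrogenase genes ALDH3A1 12.8-fold in GRO-seq and ALDH1A3 4.17-fold in RNA-seq, and TIPARP 1.99-fold in RNA-seq. AHR-induced genes were higher in 5 of 13 cases in GRO-seq (adjusted p = 0.038) and 10 of 15 in RNA-seq (adjusted p = 0.0019). Among the more precisely measured genes, which hold 3 and 5 of them, 2 and 4 were higher and neither call was kept (adjusted p = 0.295 and 0.33).

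GRO-seq contrast 3 showed p53 target and immediate early genes higher and cell cycle genes lower. Of 30 p53 targets, 19 were higher and none was lower (adjusted p = 1.7e-11), among them TP53INP1 (4.39-fold), EDA2R (2.69-fold), MDM2, the negative regulator of p53 (2.56-fold), and XPC (2.39-fold) in the authors' deposited table. Of 21 immediate early genes, 14 were higher (adjusted p = 4.0e-09), led by EGR3 (46.1-fold) and EGR1 (6.22-fold). Of 33 cell cycle genes, 13 were lower and none was higher (adjusted p = 3.1e-05), including E2F1 (0.171-fold), CDC45 (0.278-fold) and MCM5 (0.284-fold), a call lost among the more precisely measured genes, where 7 of 18 were lower (adjusted p = 0.11). EMT transcription factor genes were lower in 6 of 17 cases (adjusted p = 0.027), and in 4 of 8 among the more precisely measured genes (adjusted p = 0.165), with ZEB2 0.234-fold and TWIST2 0.351-fold. Other large GRO-seq changes were those of WNT4 (39.1-fold), the ubiquitin ligase gene FBXO32 (35.3-fold), KRT1 (33.2-fold) and the p53 family gene TP73 (23.6-fold), against CAMK2N1 (0.0460-fold), AKAP12 (0.0598-fold) and CDH4 (0.0652-fold) in the authors' deposited table.

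In RNA-seq contrast 3, cell cycle genes went the other way than in GRO-seq, while more immediate early genes were higher than lower in both. Cytokine genes in GRO-seq had 5 of 17 higher and none lower (adjusted p = 0.11 for higher, Fisher's exact test). The counts that follow are those of RNA-seq. Cell cycle genes were higher in 15 of 33 cases and lower in 3 (adjusted p = 0.0033), with RRM2 1.49-fold and CCNE2 1.63-fold. The p53 targets did not pass (9 of 30 higher and 6 lower, adjusted p = 0.33), with CDKN1A 1.48-fold and SESN2 0.652-fold in the authors' deposited table. Cytokine genes were higher in 11 of 19 cases and lower in 1 (adjusted p = 0.0019 for higher), including IL24 (4.11-fold), IL1B (2.15-fold), LIF (1.86-fold) and IL1A (1.67-fold). Immediate early genes were higher in 9 of 21 and lower in 4 (adjusted p = 0.038 for higher), including IER3 (1.91-fold). Cholesterol synthesis genes were higher in 11 of 19 cases and lower in 2 (adjusted p = 0.0019 for higher). Oxidative stress genes were higher in 8 of 17 and lower in 4 (adjusted p = 0.033 for higher). The increases were small, such as 1.29-fold for IDI1 and 1.37-fold for TXNRD1. Epithelial markers were lower in 13 of 33 cases (adjusted p = 0.031), with CLDN1 0.380-fold and TJP3 0.450-fold, luminal markers in 6 of 9 (adjusted p = 0.013), and basal markers in 7 of 14 with 5 higher (adjusted p = 0.033). Epithelial markers lay on the other side in GRO-seq contrast 3, with a median of 0.50 (percentile 99.98 among random lists). There, 5 of 34 were higher and 1 lower, which did not pass (adjusted p = 0.77 for higher, Fisher's exact test). CHAC1, a glutathione-degrading enzyme gene (0.0852-fold), FLRT1 (0.117-fold) and PPARGC1A (0.134-fold) were among the lowest, and RNF223 (7.04-fold) and SERPINB2 (4.53-fold) among the highest in the authors' deposited table. CDH1 was not called, VIM was 0.913-fold and SNAI2 1.18-fold. None of the 9 RNA-seq list calls of this contrast was kept among the more precisely measured genes, where the adjusted p ranged from 0.108 to 0.55, and with a 2-fold minimum all but the AHR call were lost, with 0 of 33 cell cycle and 0 of 19 cholesterol genes left. Fewer members were tested among the more precisely measured genes, and the shares called did not all fall: cytokine genes were higher in 6 of 7 cases, cholesterol genes in 10 of 16 and AHR-induced genes in 4 of 5, and luminal markers were lower in 3 of 4.

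**Figure D3:**
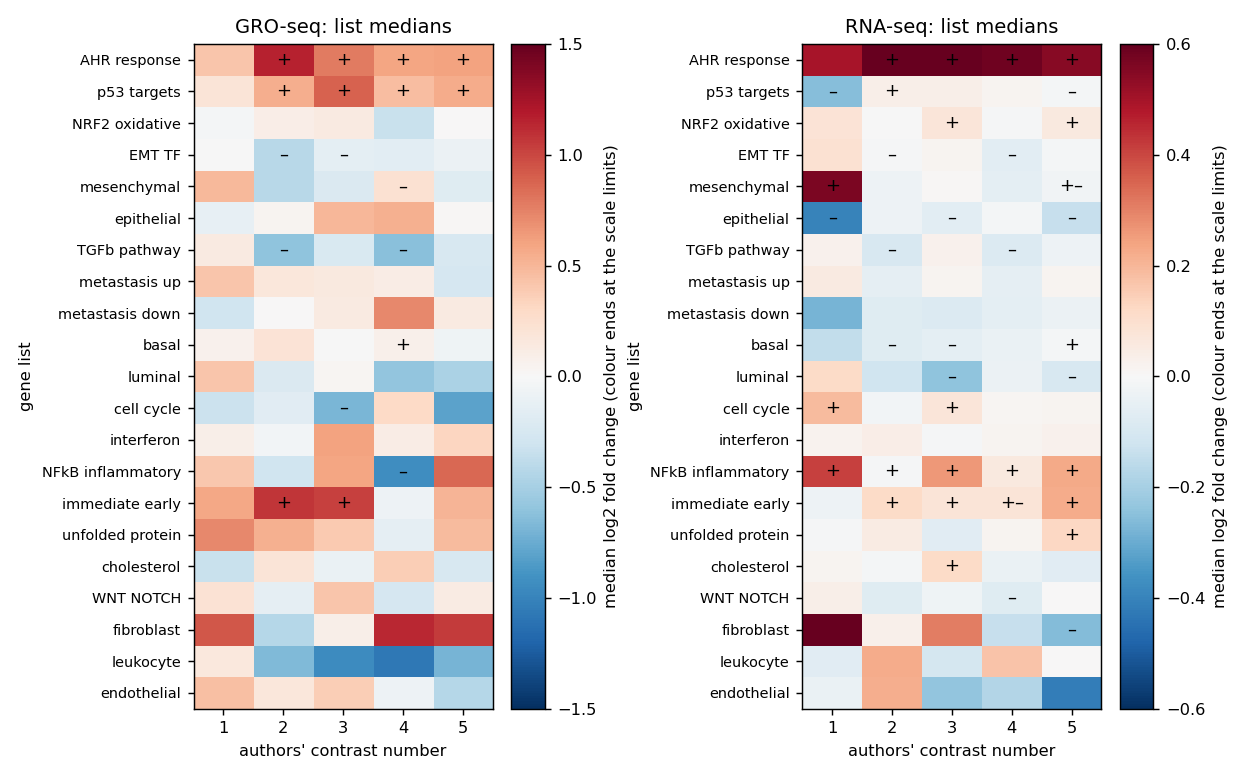
Median log2 fold change (colour, with a separate scale for each assay) of the 21 gene lists in the 5 contrasts, with a plus where more members were higher and a dash where more were lower than among all other genes (adjusted p under 0.05). The AHR list carries a plus in contrasts 2 to 5 of both assays, and its GRO-seq median is 1.16 in contrast 2.

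AHR target genes were also higher in contrasts 4 and 5. In contrast 4, CYP1A1 was 48.0-fold higher in GRO-seq (log2 5.58 ± 0.72, adjusted p = 5.3e-05) and 45.6-fold higher in RNA-seq (log2 5.51 ± 0.19, adjusted p = 1.7e-19) in the authors' deposited table. AHR-induced genes were higher in 6 of 13 cases in GRO-seq (adjusted p = 9.6e-07, and 0.44 among the more precisely measured genes, which hold 3 of them) and 11 of 15 in RNA-seq (adjusted p = 1.4e-11). TGF-β pathway genes were lower in 6 of 25 cases in GRO-seq (adjusted p = 2.4e-05), including INHBA (0.110-fold) and TGFB2 (0.350-fold), and in 7 of 25 in RNA-seq (adjusted p = 0.0016). EMT transcription factor genes were lower in 6 of 18 cases in RNA-seq (adjusted p = 0.0016), including SOX9 (0.483-fold) and SNAI2 (0.779-fold), and WNT and Notch genes in 5 of 20 (adjusted p = 0.016), including DKK1 (0.476-fold). In GRO-seq, basal keratin genes KRT5 (3.36-fold), KRT14 (2.74-fold), KRT17 (2.84-fold) and KRT6B (4.16-fold) were higher in the authors' deposited table, with 5 of 14 basal markers higher (adjusted p = 2.4e-05, and 0.069 among the more precisely measured genes). The p53 targets were higher in 5 of 30 cases (adjusted p = 0.0010), which did not hold with a 2-fold minimum (0 genes, adjusted p = 1.0). Cytokine genes were lower in 3 of 17 cases in GRO-seq (adjusted p = 0.017), including IL24 (0.0688-fold), and higher in 4 of 19 in RNA-seq (4 lower, adjusted p = 0.033, and 0.40 among the more precisely measured genes), including IL24 (2.60-fold). At an adjusted p under 0.01, the GRO-seq calls for cytokine genes (1 of 17), p53 targets (1 of 30) and mesenchymal markers (2 of 38) were lost (adjusted p = 0.45, 0.63 and 0.14). With a 2-fold minimum, the AHR call alone was left of the 7 RNA-seq list calls of contrast 4. Mesenchymal markers were lower in 4 of 38 cases in GRO-seq (TNC, TAGLN, COL4A1 and COL4A2, adjusted p = 0.018) while the list's median was 0.22, and that call did not hold among the more precisely measured genes (adjusted p = 0.68). Immediate early genes went both ways in RNA-seq, with 6 of 21 higher and 6 lower (adjusted p = 0.0016 and 0.0033). Epithelial markers had a median of 0.53 in GRO-seq (percentile 100 among random lists), against -0.01 in RNA-seq. By counts they did not pass in GRO-seq, with 3 of 34 higher and none lower (adjusted p = 0.098 for higher, Fisher's exact test).

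Contrast 5 had 35 GRO-seq calls, of which IL6, an inflammatory cytokine gene (16.8-fold), CYP1B1 (6.29-fold) and AHRR (5.36-fold) had the largest folds and the actin-binding protein gene TAGLN (0.201-fold) the smallest in the authors' deposited table. CYP1A1 was 2.90-fold in GRO-seq (adjusted p = 0.49) and 4.79-fold higher in RNA-seq (adjusted p = 8.5e-10). AHR-induced genes were higher in 2 of 13 cases in GRO-seq (adjusted p = 0.0041) and p53 targets in 2 of 30 (adjusted p = 0.011), and neither call was kept among the more precisely measured genes (adjusted p = 1.0 and 0.059). No GRO-seq gene had an adjusted p under 0.01, while 1702 had an unadjusted p under 0.05. In RNA-seq, SATB1 was 1.49-fold higher (log2 0.57 ± 0.03, adjusted p = 1.6e-14). Epithelial markers were lower in 17 of 33 cases (adjusted p = 3.8e-07), with CLDN1 0.551-fold and DSG3 0.728-fold. Mesenchymal markers went both ways, with 10 of 39 higher (adjusted p = 0.025) and 11 lower (adjusted p = 0.013), including COL3A1 (0.362-fold) and COL1A1 (0.661-fold). Fibroblast markers were lower in 4 of 9 cases (adjusted p = 0.040). Cytokine genes were higher in 11 of 19 cases (adjusted p = 1.2e-05), immediate early genes in 11 of 21 (adjusted p = 3.0e-05), AHR-induced genes in 9 of 15 (adjusted p = 4.4e-05), oxidative stress genes in 7 of 17 (adjusted p = 0.0088), unfolded protein response genes in 6 of 14 (adjusted p = 0.011) and basal markers in 6 of 14 (adjusted p = 0.011, median -0.01). Some members of these lists were lower, among them 3 oxidative stress genes and 3 basal markers. The p53 targets (9 of 30, with 4 higher, adjusted p = 0.017 for lower) and luminal markers (4 of 9, with 1 higher, adjusted p = 0.040 for lower) were lower. Among the more precisely measured genes, with fewer members tested, the oxidative stress (6 of 13), basal (5 of 11), p53 (6 of 24), luminal (3 of 4), fibroblast (1 of 1) and lower mesenchymal (3 of 16) calls were lost (adjusted p = 0.11, 0.18, 0.57, 0.085, 0.42 and 0.96). At an adjusted p under 0.01 the p53 (6 of 30), luminal (2 of 9) and higher mesenchymal (7 of 39) calls were lost, and with a 2-fold minimum only the AHR call was left.

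Counts adjusted over the list alone were larger for several lists. In RNA-seq contrast 4, TGF-β pathway genes had 10 lower and 3 higher adjusted over the list alone, against 7 and 0 over all genes, mesenchymal markers 7 lower against 3, p53 targets 7 higher against 4 and immediate early genes 9 higher against 6. Basal markers had 9 lower in RNA-seq contrast 2, against 6. In RNA-seq, the AHR list had 12, 11, 11 and 9 members higher in contrasts 2 to 5 adjusted over the list alone. In GRO-seq, the p53 targets had 15, 23, 9 and 13 members higher in contrasts 2 to 5 adjusted over the list alone, against 10, 19, 5 and 2 over all genes. Cell cycle genes had 14 of 33 lower in GRO-seq contrast 5 adjusted over the list alone and 0 over all genes. For the mesenchymal and epithelial lists in RNA-seq contrast 1 these counts were 26 higher and 23 lower.

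Fold changes differed between contrasts of the same table for many genes. In RNA-seq, 65 genes differed between contrasts 4 and 2 (7 higher and 58 lower in contrast 4) and 417 between contrasts 5 and 3 (189 higher and 228 lower in contrast 5). CYP1A1, CYP1B1, TIPARP and ALDH1A3 were among those lower in contrast 4 than in contrast 2, and in contrast 5 than in contrast 3. The log2 difference for CYP1B1 was -1.06 ± 0.08 (adjusted p = 7.6e-10) and -0.96 ± 0.09 (adjusted p = 1.2e-08). In GRO-seq, 60 and 75 genes differed, and the difference for CYP1A1 was not past the threshold (log2 difference -1.77 ± 1.05, adjusted p = 0.49, and -0.46 ± 1.20, adjusted p = 0.92). Among the genes that differed in GRO-seq, chosen after their values were seen, were EGR1 (4.04-fold in contrast 2 and 1.03-fold in contrast 4, adjusted p = 0.019) and NEB (19.0-fold and 3.36-fold, adjusted p = 0.014) in the authors' deposited table. In RNA-seq, 2352 genes differed between contrasts 3 and 2 and 1507 between contrasts 5 and 4, against 4 and 12 in GRO-seq. The GRO-seq counts are limited by its larger standard errors. For these pairs, 617 and 711 GRO-seq genes had an unadjusted p under 0.05 in the difference test, fewer than the 737 of chance. The test thus called too few genes there, and the low counts do not show that differences are absent. For CDH1 no difference was called. Its RNA-seq log2 differences had 95% intervals from -0.05 to 0.12 and from -0.09 to 0.08, and in GRO-seq contrast 4 exceeded contrast 2 by 1.40 ± 0.53 (adjusted p = 0.24). These tests took contrasts as independent, which contrasts with a group in common are not.

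Under the same contrast number, GRO-seq and RNA-seq moved together in contrasts 2 and 4 and apart in contrast 3. Across numbers, RNA-seq contrasts 2 and 4 had positive Spearman correlations with every GRO-seq contrast. RNA-seq contrasts 3 and 5 had negative ones with every GRO-seq contrast. The most negative values were those of RNA-seq contrast 1 with GRO-seq contrasts 2 (-0.24) and 3 (-0.23), so the opposition is not particular to contrast 3. Across the 13771 genes in both tables, which are not independent replicates, the Spearman correlation of log2 fold changes was 0.038, 0.25, -0.12, 0.13 and -0.063 in contrasts 1 to 5, and the Pearson correlation was 0.29, 0.19, -0.13, 0.072 and -0.035. Of 646 genes called in both assays in contrast 2, 540 (83.6%, exact 95% interval 80.5% to 86.4%) went the same way, as did 96 of 110 in contrast 4 (87.3%). In contrast 3, 422 of 1251 did (33.7%, interval 31.1% to 36.4%), with 398 genes higher in GRO-seq and lower in RNA-seq, where independent lists would share 258. In contrasts 1 and 5, 44 of 82 and 7 of 18 went the same way. The following genes were chosen after their values were seen, from the 12 called genes of each kind with the largest changes in both assays. In contrast 3, PPARGC1A (17.4-fold and 0.134-fold), TP73 (23.6-fold and 0.221-fold), FGF1 (11.3-fold and 0.286-fold) and TNFSF11 (4.66-fold and 0.142-fold) were higher in GRO-seq and lower in RNA-seq in the authors' deposited table, whereas CYP1B1, AHRR (5.82-fold and 3.62-fold) and IL20 (9.90-fold and 2.19-fold) were higher in both. In contrast 2, VIPR1 (6.71-fold and 5.82-fold) and CD7 (8.73-fold and 8.36-fold) were higher and DKK1 (0.200-fold and 0.446-fold) lower in both. Among the more precisely measured genes the correlation was -0.071 in contrast 1, 0.22 in contrast 4 and -0.12 in contrast 5.

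**Figure D4:**
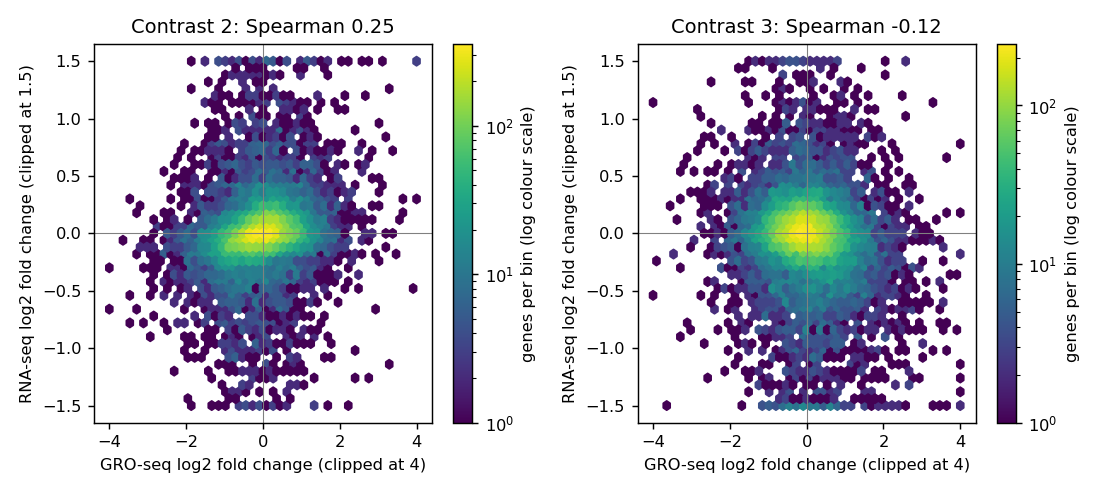
GRO-seq log2 fold change (x axis, clipped at 4) against RNA-seq log2 fold change (y axis, clipped at 1.5) of the 13771 genes in both tables for contrast 2 (left) and contrast 3 (right), with the number of genes per bin as colour on a log scale. The Spearman correlation is 0.25 in contrast 2 and -0.12 in contrast 3.

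Contrasts within a table overlapped. In GRO-seq, 670 genes were higher in both contrasts 2 and 3 and 750 lower in both, against 104 and 103 for independent lists, and 5 went opposite ways. In RNA-seq, 877 were higher and 749 lower in both, against 273 and 265, and 193 went opposite ways. Contrasts 1 and 3 had 1325 genes higher and 1440 lower in both in RNA-seq, against 658 and 569. Contrasts 1 and 2 had 390 higher and 524 lower in both, against 346 and 309, and 711 opposite, against 655. In GRO-seq, contrasts 1 and 3 had 32 genes higher and 61 lower in both, and contrasts 1 and 2 had 24 and 45. For 2 contrasts with a group in common and no effect, a Pearson correlation of 0.50 was put into the simulation. The simulated covariances follow from that value and the implied standard errors, not from the libraries. The observed values for contrasts 2 and 3 were 0.72 in GRO-seq (covariance 0.438 against 0.101 simulated) and 0.49 in RNA-seq (0.0729 against 0.0455). For contrasts 1 and 2 they were 0.46 in GRO-seq (0.213 against 0.10) and 0.19 in RNA-seq (0.0561 against 0.0426), and for contrasts 1 and 3 they were 0.57 (0.281 against 0.10) and 0.29 (0.0975 against 0.0455). Where contrasts have control libraries in common, part of the excess over independent lists comes from them, and the controls could not be split here.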

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

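A test of the difference between responses was planned before the data were examined, but the pairs of numbered contrasts it was run on were chosen after the results had been seen. Which groups contrasts 2 to 5 compare is not stated in the table headers, so the pairs 4 with 2 and 5 with 3 are tests between numbered contrasts. Among the 7 genes named in advance, 4 had RNA-seq fold changes that differed between the contrasts of a pair. For CYP1A1, the log2 fold change was lower by -2.10 ± 0.29 in contrast 4 than in contrast 2 (adjusted p = 5.4e-05) and by -2.91 ± 0.30 in contrast 5 than in contrast 3 (adjusted p = 1.2e-07). CYP1B1 gave -1.06 ± 0.08 (adjusted p = 7.6e-10) and -0.96 ± 0.09 (adjusted p = 1.2e-08). For TIPARP the differences were -0.50 ± 0.05 (adjusted p = 5.0e-08) and -0.52 ± 0.05 (adjusted p = 2.5e-08). SATB1 was higher by 0.83 ± 0.19 in contrast 5 than in contrast 3 (adjusted p = 0.012). In GRO-seq, where the standard errors are several times larger and SATB1 was not analysed, the differences for CYP1A1, CYP1B1 and TIPARP were not past the threshold, which does not show that they are absent. No biological explanation was tested for these differences.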

How the results depend on the processing

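Tests on the more precisely measured genes and without chromosomes 15 and 17 were chosen after seeing the data. No paired analysis was possible because the deposited tables hold no values per library, and for the same reason DESeq2, low count filters, pseudocounts, leaving out replicates, filters on level and counts over other splits of the libraries were not run. Depth is unknown, so the standard error stands in for it, and GRO-seq is limited most. Adjusting over all rows and leaving out chromosomes 15 and 17 kept all 10 counts of changed genes within 1.5 times. These are weak checks. In GRO-seq 0 rows lack a symbol, so adjusting over all rows could not change its counts, and in RNA-seq it adds 0.994% of rows. Leaving out the 2 chromosomes also kept most genes.

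Stricter and looser thresholds moved counts by construction. At an adjusted p under 0.01, GRO-seq called 1, 1042, 1318, 149 and 0 genes in contrasts 1 to 5, and RNA-seq 1624, 660 and 2071 in contrasts 2, 4 and 5. At 0.1, GRO-seq called 333, 813 and 93 genes in contrasts 1, 4 and 5. With at least 2-fold as well, the counts were 1156, 1443 and 297 in GRO-seq contrasts 2 to 4, and 1042, 117, 287, 43 and 144 in RNA-seq. At 1.5-fold, RNA-seq had 1619, 247, 664, 80 and 328. Among the more precisely measured genes, contrast 1 had 67 calls in GRO-seq and 4346 in RNA-seq. List calls under a 2-fold minimum numbered 1 in GRO-seq contrasts 1 and 5 (0 and 2 without it) and 1 in each of RNA-seq contrasts 2 to 5 (7, 9, 7 and 12 without it). At 0.01 they numbered 3 and 0 in GRO-seq contrasts 4 and 5 (from 6 and 2) and 8 in RNA-seq contrast 1 (from 5). Among the more precisely measured genes they numbered 1, 2, 2, 3 and 0 in GRO-seq and 3, 0 and 6 in RNA-seq contrasts 2, 3 and 5. Of 40 RNA-seq list calls, 34 were lost with a 2-fold minimum and 21 among the more precisely measured genes; of 18 GRO-seq list calls, 2 and 11 were. Genes that differed at 0.1 numbered 164 (contrast 4 minus 2), 190 (5 minus 3), 15 (3 minus 2) and 48 (5 minus 4) in GRO-seq and 696 (5 minus 3) in RNA-seq. At 0.01 the genes higher and lower in both were 0 and 1 for GRO-seq contrasts 1 and 2, 0 and 1 for 1 and 3, 296 and 346 for 2 and 3, and in RNA-seq 181 and 287 for 1 and 2, and 432 and 386 for 2 and 3. The correlation of GRO-seq with RNA-seq over genes called in either assay was 0.10, 0.38, -0.19, 0.29 and -0.12 in contrasts 1 to 5. Over the more precisely measured genes it was 0.31 in contrast 2, -0.10 in contrast 3, 0.22 in contrast 4, -0.12 in contrast 5 and, with its sign turned, -0.071 in contrast 1; the cause was not tested. Of the 584 values of named genes, 98 were not called at 0.01 and 2 more were called at 0.1.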

Other observations

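The tests here of interaction terms, the contrasts' layout, the dosage of chromosome 15, the segment of chromosome 9, fibroblasts and another number for RNA-seq contrast 3 were chosen after the results were seen. Several lists passed in no contrast of either assay. In RNA-seq contrast 1, genes earlier linked to raised expression by SATB1 in breast cancer were higher in 6 of 15 cases and lower in 2, those linked to lowered expression higher in 1 of 6 and lower in 4, interferon genes higher in 9 of 26 and lower in 7, leukocyte markers higher in 1 of 7 and endothelial markers higher in 1 of 6 and lower in 3. Interferon genes held some of the largest changes all the same, with MX2 84.5-fold and XAF1 44.5-fold higher and BST2 0.0977-fold in the authors' deposited table. There were 30 genes at least 64-fold higher and 3 as far lower in RNA-seq contrast 1. Of the 30, 27 were in the GRO-seq table, 25 of them above 1, with a median of 4.48-fold, 13 at an unadjusted p under 0.05 and none called. Gene length went with fold change weakly, and in opposite directions in contrasts 2 to 5. The Spearman correlation was -0.12 in GRO-seq and 0.15 in RNA-seq in contrast 2, and -0.055 and 0.17 in contrast 4. In contrast 5 it was -0.050 and 0.013. Both assays were slightly negative in contrast 1 (-0.028 and -0.0096).

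The identity of the contrasts was tested on the structure of the tables, not on the condition of any library. Contrasts 4 and 5 as interaction terms of 4 groups would have larger standard errors than contrast 1, and the ratio farthest from 1 was 1.02, which argues against it. Chance correlations were taken over genes with a large unadjusted p in all 5 contrasts (2699 in GRO-seq and 1251 in RNA-seq). If contrasts 1, 2 and 3 shared a denominator, and the numerator of contrast 1 were the denominator of contrasts 4 and 5, they would be positive, negative or near 0 in a set pattern. The values expected were simulated for a single pair of contrasts at a time, unlike the choice of genes on all 5. Of 10 pairs, 9 were nearest to that pattern in GRO-seq and 7 in RNA-seq, so this layout stays open. A hypothesis under that layout is that contrast 1 may set SATB1 cells against vector cells, contrasts 2 and 3 exposed against untreated vector cells, and contrasts 4 and 5 exposed against untreated SATB1 cells; the order of 3 hours and 3 days stays open.

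Fold changes went with chromosome position, most in contrast 1 for RNA-seq. Other contrasts also had chromosomes beyond all random sets, such as chromosome 16 (median -0.05 in RNA-seq contrast 2 and -0.17 in GRO-seq contrast 2, and -0.09 in GRO-seq contrast 1), chromosome 22 (-0.06 in RNA-seq contrast 2) and chromosome 8 (0.17 in GRO-seq contrast 2). In GRO-seq contrast 5, chromosomes 16, 19 and 22 lay below all random sets (-0.08, -0.09 and -0.14). Chromosomes 4, 5, 6 and 13 lay above all there (0.08, 0.10, 0.09 and 0.14). Chromosomes 19 and 22 also lay below all in GRO-seq contrasts 2 and 3. No explanation was tested for these shifts, which bear on reading the shift of any 1 chromosome as dosage. The intervals and random sets treat the genes of a chromosome as independent, which neighbouring genes may not be, so both may be too narrow. Of 475 chromosome 15 genes, 78.5% lay above 1 in RNA-seq contrast 1 (95% interval 74.6% to 82.0%), with a median log2 fold change of 0.20, and a length trend is argued against because 10000 random gene sets matched on length reached at most 0.054. A different dosage of chromosome 15 in the cells on the 2 sides could not be told apart from other sources, since its GRO-seq median of 0.05 lay at percentile 99.0 of matched sets but 2 other chromosomes lay as high, chromosome 8 (0.16, 66.8% above 1) and X (0.09). In GRO-seq contrast 4, the chromosome 15 median was -0.08 (percentile 0.03). Chromosome 8 lay above all random sets in GRO-seq contrasts 2, 3 and 4 too. In RNA-seq contrast 1, chromosome 17 also lay beyond all random sets, with a median of 0.07 (61.0% above 1, and 76.5% from 60 to 80 Mb) against a highest random median of 0.05, while its GRO-seq median of 0.02 (51.5% above 1) lay at percentile 72.9. On chromosome 9 from 21802636 to 22009313, MTAP (31.1-fold), CDKN2A (301-fold) and CDKN2B (50.4-fold), a region reported as deleted in MCF10A cells, were higher in RNA-seq while 21 genes within 5 Mb had a median absolute log2 fold change of 0.24, although PLIN2 (501-fold), ADAMTSL1 (21.1-fold) and BNC2 (4.27-fold) lie among them; a segment present in the cells of 1 side only may account for this, a hypothesis that transcript levels cannot settle, and neither the identity of the cell lines, clonal difference nor SATB1 itself was tested. A different line or clone on 1 side would change what each contrast 1 value means, the EMT, cell cycle and p53 shifts included. In GRO-seq, CDKN2A (12.3-fold, adjusted p = 0.27) and CDKN2B (7.54-fold, adjusted p = 0.089) were above 1 in the authors' deposited table but not called. Fibroblasts among the cells, a candidate source of COL1A2 and COL3A1 (at least 379-fold), stay open. LUM, PDGFRA and PDGFRB were not called, and their upper 95% bounds reach 7.17-fold at most. They were picked from the list after their values were seen, so they cannot decide the question. Of the other fibroblast markers, COL1A1, COL1A2, COL3A1, THY1 (137-fold) and FAP (1.53-fold) were higher and DCN was lower. These genes of chromosome 9 and the fibroblast markers singled out were chosen after their values were seen.

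The opposed directions of GRO-seq and RNA-seq in contrast 3 were weighed against 3 technical explanations. Opposition was not confined to that contrast, since RNA-seq contrast 1 had a correlation of -0.24 with GRO-seq contrast 2, which was not examined further. Imprecise genes are argued against by a Spearman correlation of -0.10 over the 5228 genes measured more precisely in both assays, and opposite length trends by a mean of -0.12 within 10 length bins. A different numbering in the 2 tables stays open: the test planned for it gave 0.17 as the highest correlation of GRO-seq contrast 3 with any RNA-seq contrast (contrast 4). The highest correlation of RNA-seq contrast 3 with any GRO-seq contrast was -0.018 (contrast 5, with 35 GRO-seq calls), against -0.12 under the numbers given. With GRO-seq contrasts 1, 2 and 4 it was -0.10, -0.09 and -0.06. Another number for RNA-seq contrast 3 would thus give no positive relation, and contrast 1 or 2 would leave most of the opposition. No biological explanation, such as a delay between nascent and accumulated RNA, was tested, nor was a difference in the culture or day of the 2 assays, which the labels do not give.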
